A study of Mus musculus with 18 samples.

How the data were processed

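Bulk RNA sequencing of 18 mouse heart libraries was re-analysed. Per the labels' protocols, male C57BL/6J mice underwent ligation of the left anterior descending coronary artery, and atria, infarcted left ventricle (LV) and non-infarcted LV were collected 3 days later; RNA was prepared with TRIzol and libraries with a stranded TruSeq kit for polyadenylated RNA. Groups are region and treatment (liraglutide or PBS) as the labels give them, with 3 biological replicates each. Sham-operated mice are mentioned in the labels, but no such sample is in the series, so no comparison with uninfarcted hearts was possible. Dose, schedule and start of treatment, the number of animals, the sequencing batch and the read length are not given in the sources used here.

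The deposited table holds raw counts per gene symbol for all 18 libraries, whole numbers throughout. Per the submitters' processing notes, STAR 2.7.9a, DESeq2 (version not given) and the mm10 build were used; the counting tool, its strand setting and the annotation are not given in the sources used here. Genes that overlap on opposite strands or share sequence, such as Hspa1a and Hspa1b or the pseudogene Rps4l and its parent, may therefore share reads. Of 25230 symbols 5537 were at 0 in every library. Library totals ran from 4280459 (infarcted LV, PBS replicate 3) to 21853482 counts (atria, liraglutide replicate 3), with a median of 11586459.5. By group they were 13849938 to 21853482 for atria with liraglutide, 6262832 to 18839472 for atria with PBS, 8211804 to 11181101 and 4280459 to 10772531 for infarcted LV, and 11991818 to 15698897 and 8341694 to 17016262 for non-infarcted LV. A count of 3 in a library equals 0.137 to 0.701 CPM, which is the floor used for bounds. Libraries of a group were checked for duplicates: over the 18 pairs within groups, the chi-square per degree of freedom between their counts was 2.55 to 58.96, so none repeats another.

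Each comparison was fitted on its own 6 libraries in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, TMM factors, robust dispersions, quasi-likelihood F tests (4 residual degrees of freedom before moderation) and Benjamini-Hochberg adjustment over all tested genes, with a threshold of 0.05. Group means are therefore normalized within a comparison and differ slightly between comparisons, while values of single libraries are CPM of the library total. Standard errors are the absolute log2 fold change over the square root of F. The 5 comparisons are liraglutide against PBS in each region, and, in PBS animals, infarcted against non-infarcted LV and atria against non-infarcted LV. Differences of the liraglutide effect between regions were tested as contrasts in a fit of all 18 libraries.

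Gene lists, 38 with 588 symbols, were fixed before the data were examined. They cover cardiomyocyte, stromal, immune and neighbouring cell types, inflammation, metabolism, stress and hormone or cAMP responses. Of the symbols 570 matched as written and 1 under another name, and 17 were not found, 13 of them the mitochondrially encoded genes, which the table lacks. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation, under which 0 lists passed in any of the 5 comparisons (lowest adjusted p = 0.137). Atrial and ventricular cardiomyocyte markers did not pass it in atria against non-infarcted LV either. Missing it therefore does not show that a list is unchanged. Members were also counted at a threshold adjusted over the list alone. Some genes are in more than 1 list, and many stromal and metabolic markers are expressed by several cardiac cell types.

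Named genes follow a rule fixed beforehand. Among genes past the threshold with a mean count of at least 50 and groups that do not overlap, the 12 with the largest fold change in each direction are named, or the 6 with the smallest p where fewer than 6 pass; for contrasts between regions the 5 with the smallest p in each direction; up to 4 members with the smallest p of a list described; and always Glp1r, Nppa, Nppb, Myh6 and Myh7. Unnamed gene models, immune receptor segments and ribosomal pseudogenes are not named. Genes chosen after their values were seen are marked as such. Locations come from the GENCODE annotation of GRCm38 (mm10), in which Pwwp3b was not found under that symbol.

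Sensitivity was checked with DESeq2 1.42.0, voom with sample quality weights, RLE factors, no filter, a stricter filter (CPM of 1 or more in at least 3 libraries), all 18 libraries in the fit, a threshold on the log2 fold change of 1, a replicate block (the replicate number for liraglutide against PBS, the number in the labels, here called the animal number, between regions and in the contrasts of the effect), and each library left out in turn. The labels do not say that this number marks 1 animal. Leaving out 2 atrial libraries with markers of other tissue, summing both LV regions per animal number, and fitting the 12 LV libraries alone, were added after the data were seen. Whether equal numbers in the labels mark tissues of 1 animal was checked with the correlation across genes of each library's deviation from its group mean (pseudocount of 1 CPM, mean count of at least 20; taken as paired where every value is above 0.1). It was 0.152 to 0.171 for infarcted and non-infarcted LV with PBS, 0.131 to 0.173 with liraglutide, and 0.108 to 0.197 for atria and non-infarcted LV with PBS, each library being closest to its own number in all 3 cases; it was 0.000181 to 0.156 for atria and infarcted LV with PBS, -0.0619 to 0.0689 with liraglutide, and -0.0764 to -0.00606 for atria and non-infarcted LV with liraglutide.

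The code was tested on simulated data with the depth and dispersion of these libraries. Of genes given a 1.5-fold, 2-fold or 4-fold change, the share called was 19.7, 75.8 and 93.9% for liraglutide in atria, 66.7, 86.4 and 98.5% in infarcted LV, 68.7, 85.1 and 98.5% in non-infarcted LV, 63.6, 85.1 and 100% for infarcted against non-infarcted LV, and 32.3, 82.1 and 97% for atria against non-infarcted LV. False calls were 6 of 131, 14 of 180, 10 of 178, 16 of 180 and 11 of 151 calls in the same order, above 5% in all but the first. A list moved on purpose was called by camera in all 5, and 0 of 20 random lists were. Genes were simulated independently of each other, so this cannot show how often camera falsely calls lists of correlated genes. No library was left out of the comparisons. Atria and infarcted LV were compared only in the contrasts of the liraglutide effect.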

Results

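Messenger RNA was measured 3 days after ligation of the left anterior descending coronary artery in atria, infarcted left ventricle (LV) and non-infarcted LV of male mice given liraglutide, an agonist of the GLP-1 receptor, or PBS. Every group holds 3 libraries, which the labels call biological replicates. Levels are mean CPM ± SD over n = 3 per group, fold changes are on the log2 scale with a standard error (SE), and adjusted p values of genes come from edgeR. Region set the libraries apart: the first component of all 18 libraries placed the atria at -66.9 to -51.3 and the LV libraries at 28.7 to 35.8, and the second parted infarcted (-39.8 to -25.3) from non-infarcted LV (27.8 to 33.0). Myh6, the alpha myosin heavy chain of cardiomyocytes, took the largest share of counts in every library, 2.77 to 4.88%.

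**Figure D1:**
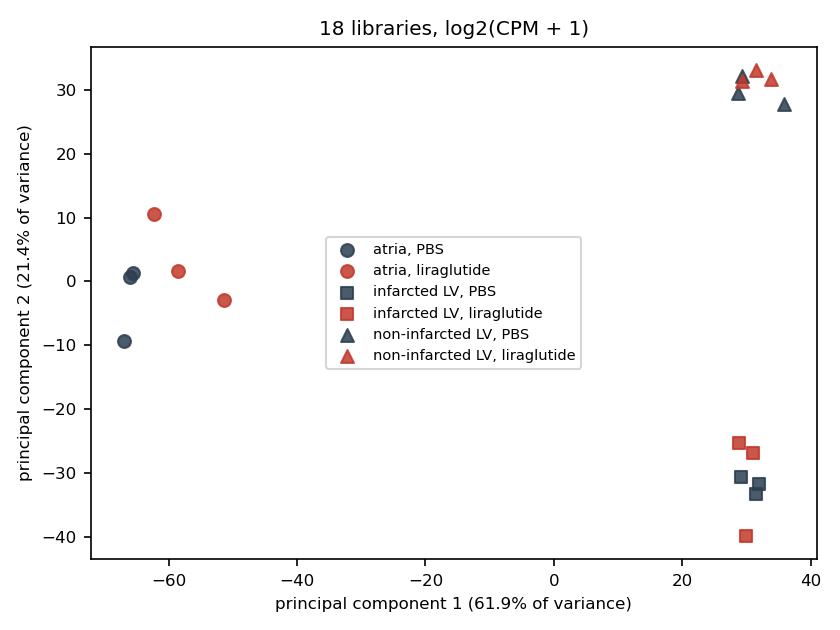
The 18 libraries on the first (x axis, 61.9% of variance) and second (y axis, 21.4%) principal components of log2(CPM + 1), computed on 12401 genes, with region by marker and treatment by colour. Atria lie at -66.9 to -51.3 on the first component and LV libraries at 28.7 to 35.8. On that component treated atria (-62.3 to -51.3) lie apart from PBS atria (-66.9 to -65.6), while in each LV region the treatments intermix on both. Treated atria with a larger median implied share of ventricular RNA lie nearer the LV: replicate 3 (8.98%) at -51.3, replicate 1 (3.27%) at -58.5 and replicate 2 (0%) at -62.3.

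With liraglutide, Irs2, which encodes an adaptor of the insulin receptor, rose in the atria from 50.2 ± 1.19 to 114 ± 10.5 CPM. This 2.26-fold change (log2 fold change 1.18, SE 0.108, adjusted p = 0.0234) made it the 1 gene of 13530 past the adjusted threshold. In single libraries Irs2 stood at 111, 93.9 and 125 CPM with liraglutide and 53.0, 52.4 and 50.5 with PBS, so all 3 treated libraries lay above all 3 controls. Irs2 lies on chromosome 8, positions 10984681 to 11008458 of GRCm38 (mm10), on the minus strand. Its fold change stayed between 1.12 and 1.26 in every alternative run. The call was lost with the replicate as a block (adjusted p = 0.117) and with all 18 libraries in the fit (0.0561). It was also lost without liraglutide replicate 1 (0.13) or 2 (0.0619), or PBS replicate 1 (0.119), 2 (0.28) or 3 (0.208).

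Other atrial genes with small p values did not pass, of which Ccn2 and Pwwp3b had a larger fold change than Irs2. Ccn2, a matricellular growth factor of the YAP pathway, stood at 1963 ± 426 CPM with liraglutide and 669 ± 135 with PBS (log2 fold change 1.56, SE 0.198, adjusted p = 0.142). Pwwp3b had 20.1 ± 3.32 and 7.31 ± 0.418 CPM (1.46, SE 0.166, adjusted p = 0.073). Tacc2, a centrosomal protein, had 528 ± 56.4 and 312 ± 21.1 CPM (0.76, SE 0.12, adjusted p = 0.363). The protease inhibitor A2m (0.88, SE 0.149) and Tent5a (0.71, SE 0.127) had the same adjusted p. On the lower side stood Fjx1 at 15.1 ± 0.35 against 25.6 ± 0.654 CPM (-0.76, SE 0.113, adjusted p = 0.281). The gap junction gene Gja5 had 47.1 ± 4.05 against 79.9 ± 12 CPM (-0.76, SE 0.136, adjusted p = 0.363). Mustn1 (-0.68, SE 0.115), the chondroitin synthases Chpf2 (-0.64, SE 0.111) and Chpf (-0.55, SE 0.101), and Aldh1a2 (-0.69, SE 0.134), which makes retinoic acid, had that adjusted p too.

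The receptor gene Glp1r was low in the atria, at 1.05 ± 0.654 and 1.09 ± 0.479 CPM (-0.02, SE 0.544, adjusted p = 0.999). In infarcted LV it gave a total of 1 count with liraglutide and 0 with PBS, and in non-infarcted LV 0 with liraglutide and 1 with PBS. The natriuretic peptide gene Nppa had 31700 ± 6250 against 33910 ± 3850 CPM in the atria (-0.10, SE 0.173, adjusted p = 0.968) and Nppb 1433 ± 355 against 928 ± 247 CPM (0.63, SE 0.234, adjusted p = 0.645). Myh6 (0.20, SE 0.161, adjusted p = 0.88) and Myh7, the beta myosin heavy chain (-0.23, SE 0.125, adjusted p = 0.784), did not pass either.

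Which atrial genes pass depends on the tool. At an unadjusted p of 0.05 edgeR gave 928 genes (485 higher, 443 lower) against 676 by chance. Groups did not overlap in CPM for 1558 genes (11.5%, chance 10%). DESeq2 called 118 genes (87 higher, 31 lower), voom with quality weights 36, edgeR on all 18 libraries 94, and edgeR without a filter 3. Leaving out liraglutide replicate 3 gave 105 genes. Without liraglutide replicate 1 or 2 or PBS replicate 2 or 3 the count was 0. Without PBS replicate 1 it was 1, a gene other than Irs2. DESeq2, voom and the 18-library fit shared 22 calls, 15 higher and 7 lower. That fit shares dispersions with the less variable LV, so its atrial p values may be too small. Chosen after their values were seen, 9 genes were also called in subsets of the same libraries, without liraglutide replicate 3 and without it and PBS replicate 2. They are Ccn2, Pwwp3b, Fhl1, Sesn1, the transcriptional regulators Arid5b (log2 fold change 1.11, SE 0.204 with all 6 libraries) and Ctbp2 (0.79, SE 0.161), the chaperone Hspa8 (0.9999, SE 0.242), the thin filament nucleator Lmod2 (1.01, SE 0.206) and the kinase Pim1 (0.74, SE 0.148).

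**Figure D2:**
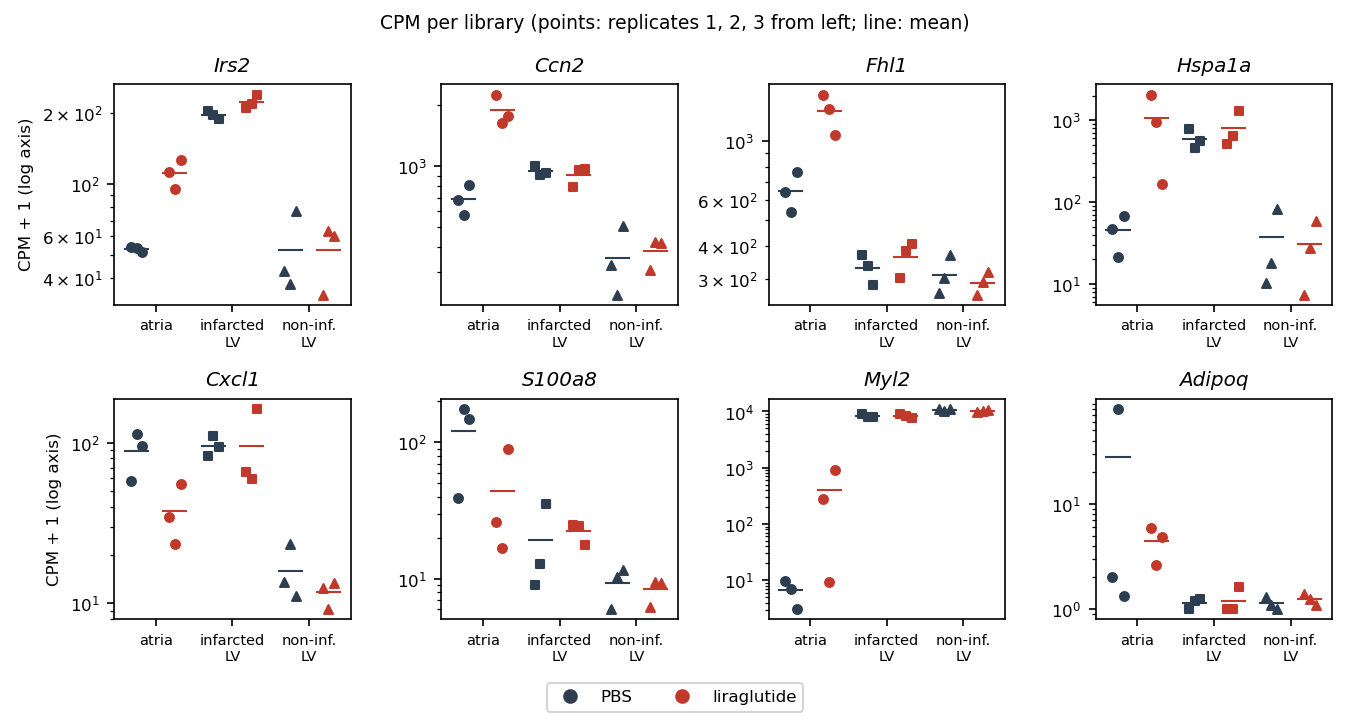
CPM + 1 on a log axis of 8 genes in the 3 regions, each point a library (replicates 1, 2 and 3 from left to right) and each line a group mean, PBS dark and liraglutide red. In the atria Irs2 stands at 93.9 to 125 CPM with liraglutide against 50.5 to 53.0, while Myl2 reaches 924 CPM in liraglutide replicate 3 and Adipoq 79.3 CPM in PBS replicate 2.

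Inflammatory genes and neutrophil markers stood lower in the atria with liraglutide. All 18 measured inflammatory cytokines and chemokines had negative fold changes (median -1.30, camera adjusted p = 8.48e-21). Cytokines had adjusted p = 0.326 with an estimated correlation. Over all genes 0 of them passed, and adjusted over the list alone 11 fell. The neutrophil attractants Cxcl2 (-2.49, SE 0.627), Cxcl3 (-2.25, SE 0.602) and Cxcl1 (-1.18, SE 0.333, with 37.2 against 84.8 CPM) and the cytokine Il11 (-2.02, SE 0.595) each had 0.0358 over the list alone.

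Of 13 neutrophil markers all were negative (median -1.03, camera adjusted p = 1.85e-10). Neutrophil markers had adjusted p = 0.461 with an estimated correlation. Over all genes 0 passed, and 1 adjusted over the list alone, the neutrophil granule protein Lcn2 (-0.90, SE 0.202, with 111 against 207 CPM). G0s2 (-0.95, SE 0.291) and the receptors Trem1 (-1.70, SE 0.644) and Il1r2 (-1.79, SE 0.683) did not pass. The granule gene S100a8, chosen after its values were seen, had 25.1, 15.8 and 87.9 CPM in the liraglutide libraries and 38.4, 176 and 147 in the PBS libraries, so the groups overlapped. The neutrophil median was -2.14 without liraglutide replicate 3 and -0.764 without PBS replicate 2, the library with adipocyte markers. Recruited monocyte and macrophage markers, 15 genes, fell as a list (median -0.393, camera adjusted p = 0.00127). Monocyte markers had adjusted p = 0.526 with an estimated correlation. Over all genes and adjusted over the list alone 0 passed (Arg1 -1.95, SE 0.518, and Cd14 -1.33, SE 0.522). That list call was lost without PBS replicate 2 (median -0.0193, adjusted p = 0.138). Its median was -0.955 without liraglutide replicate 3, -0.228 without liraglutide replicate 2 and -0.591 without PBS replicate 3.

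Genes of myocardial stress and muscle structure stood higher. Of 12 natriuretic and fetal stress genes 9 were positive (median 0.654, camera adjusted p = 1.16e-10). Fetal stress genes had adjusted p = 0.361 with an estimated correlation. Over all genes 0 passed, and 5 rose adjusted over the list alone. Besides Ccn2 these include the mechanosensing LIM protein Fhl1 (1.11, SE 0.214, with 1357 against 629 CPM), the actin-binding Xirp2 (1.23, SE 0.264, with 1712 against 732 CPM) and skeletal actin Acta1 (2.31, SE 0.552, with 4.13 against 0.789 CPM). Acta1 is also restricted to the ventricle, and the share of ventricular RNA in the treated atria, estimated from Myl2 and 7 other genes with Acta1 among them, predicts a log2 fold change of 5.09 for it, above the measured one. All 13 smooth muscle and pericyte markers were positive (median 0.401, camera adjusted p = 7.67e-08). Smooth muscle markers had adjusted p = 0.326 with an estimated correlation, and a median of 0.265 without liraglutide replicate 3. Myh11 passed adjusted over the list alone (0.72, SE 0.165, with 30.9 against 18.7 CPM) and 0 over all genes, and Myocd, a cofactor of serum response factor, had 0.84 (SE 0.259).

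Among 14 muscle atrophy and FOXO target genes the median was 0.167 (camera adjusted p = 2.58e-07). FOXO targets had adjusted p = 0.137 with an estimated correlation. Irs2 rose over all genes, and adjusted over the list alone 3 rose, with the stress sensor Sesn1 (0.83, SE 0.15, 217 against 123 CPM) and Cited2 (1.12, SE 0.249, 42.3 against 19.4 CPM). Contractile genes, 18 in number, rose as a list (median 0.176, camera adjusted p = 0.00203). These had adjusted p = 0.578 with an estimated correlation, and 0 calls over all genes or adjusted over the list alone (Csrp3 0.98, SE 0.271, and Tcap 0.57). Their call was lost without PBS replicate 2 (median 0.112, adjusted p = 0.135). Fatty acid oxidation genes, 20 in number, had a median of 0.0999 (camera adjusted p = 0.00491). Oxidation genes had adjusted p = 0.326 with an estimated correlation, and 0 calls over all genes or adjusted over the list alone (Cpt1b 0.78, SE 0.24). Without PBS replicate 1 that list did not pass (adjusted p = 0.0542). Ventricular RNA in the treated atria predicts a median of 0.0851 for it. Without liraglutide replicate 3, the library with the most, the median was 0.134 and the predicted one 0.0323.

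Heat shock genes varied strongly between the treated atria. Over 15 heat shock and oxidative stress genes the median was 0.508, with 9 positive and 6 negative (camera adjusted p = 0.0045). Heat shock genes had adjusted p = 0.461 with an estimated correlation, and 0 calls over all genes or adjusted over the list alone. Hspa1a, the inducible HSP70 chaperone, had 2061, 956 and 166 CPM with liraglutide and 46.1, 20.6 and 67.2 with PBS (4.73, SE 1.19, adjusted p = 0.538). Its partner Dnajb1 had a mean of 255 against 32.8 CPM (2.96, SE 0.862). The list lost its call without PBS replicate 1 (median 0.348, adjusted p = 0.206) and had a median of 0.166 without liraglutide replicate 1. Hspa1a has a nearly identical neighbour, Hspa1b, so the division of reads between them is uncertain.

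Markers of other tissue differed between the atrial libraries. Myl2, the ventricular regulatory myosin light chain, stood at 275, 8.3 and 924 CPM in the liraglutide atria and at 8.82, 5.95 and 2.08 in the PBS atria (6.11, SE 1.87, adjusted p = 0.639). Myl3, the ventricular essential light chain, stood at 311, 68.3 and 650 against 114, 53.9 and 68.8 CPM (2.16, SE 0.817). Over 9 ventricular markers the median was 0.384 (camera adjusted p = 0.00778). Ventricular markers had adjusted p = 0.466 with an estimated correlation. Adjusted over the list alone 1 was higher (Lbh 0.92, SE 0.175) and 1 lower (Cspg4 -0.57, SE 0.172), and 0 over all genes. Without liraglutide replicate 3 the median was -0.0193 (adjusted p = 0.463), without liraglutide replicate 2 0.692, and without PBS replicate 2 0.646. Beside them, without liraglutide replicate 3, the natriuretic and fetal stress genes had a median of 0.853.

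Adipocyte markers, 11 genes, had a median of -2.51 in the atria (camera adjusted p = 0.767). PBS replicate 2 held Adipoq at 79.3 CPM, and no other atrial library more than 4.84. The uncoupling protein of brown fat, Ucp1, was at 88.8 CPM there and at most 0.144 elsewhere in the atria. In that library the lipogenic genes Fasn (1179 CPM, others 57.3 to 74.8) and Scd1 (2472 CPM, others 31.9 to 70.3) were high too. Adipoq, Ucp1, Fasn and Scd1 were chosen after their values were seen. Cholesterol and fatty acid synthesis, 17 genes, had a median of -0.545 (camera adjusted p = 0.000171). Synthesis genes had adjusted p = 0.534 with an estimated correlation, and 0 calls over all genes or adjusted over the list alone (Scd2 0.49, Sqle -0.89). Without PBS replicate 2 their median was 0.00846 (adjusted p = 0.581).

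The remaining atrial lists past the threshold had small medians and 0 calls over all genes. Epicardial and mesothelial markers, 13 genes, had a median of -0.315 (camera adjusted p = 0.000121). Epicardial markers had adjusted p = 0.481 with an estimated correlation, and Aldh1a2 was lower adjusted over the list alone. Their median was -0.501 without liraglutide replicate 2, -0.176 without PBS replicate 2 and -0.201 (adjusted p = 0.0524) without liraglutide replicate 3. Fibroblast and extracellular matrix genes, 19 in number, had a median of -0.232 (camera adjusted p = 0.00826). Fibroblast genes had adjusted p = 0.578 with an estimated correlation, and 0 calls adjusted over the list alone (Tnc -1.13). Their call was lost without PBS replicate 1 (0.165), liraglutide replicate 2 (0.134) or PBS replicate 2 (0.123), and the median was -0.354 without PBS replicate 3. Glucocorticoid-induced genes, 16 in number, had a median of -0.0875 (camera adjusted p = 0.0265). Glucocorticoid-induced genes had adjusted p = 0.361 with an estimated correlation, and Lcn2 was lower adjusted over the list alone. Without liraglutide replicate 1 and without PBS replicate 1 the medians were -0.187 and -0.176. The call was lost without PBS replicate 2 (0.0623) and liraglutide replicate 3 (0.423).

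The other 18 of 32 lists tested in the atria did not pass (camera adjusted p from 0.0805 to 0.9). Among them were the respiratory chain (0.0805), atrial cardiomyocyte markers (0.126), GLP-1 receptor and cAMP signalling components (0.858), interferon-stimulated genes (0.858), endothelial markers (0.43), MHC class II (0.767) and resident macrophages (0.9). Median and mean differed in sign for cAMP-responsive early genes (-0.119 and 0.0427), circadian clock genes (-0.0704 and 0.00663), integrated stress genes (-0.0773 and 0.0748), PPAR targets (0.103 and -0.00318) and resident macrophages (-0.0795 and 0.00362). Too few members were measured to test lung epithelium, red cell, T and NK cell and thymocyte markers in any comparison. The same holds for B cell markers in both comparisons of atria and in the non-infarcted LV with liraglutide, and for skeletal muscle markers in the comparisons within the LV. Mitochondrially encoded genes are not in the table.

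**Figure D3:**
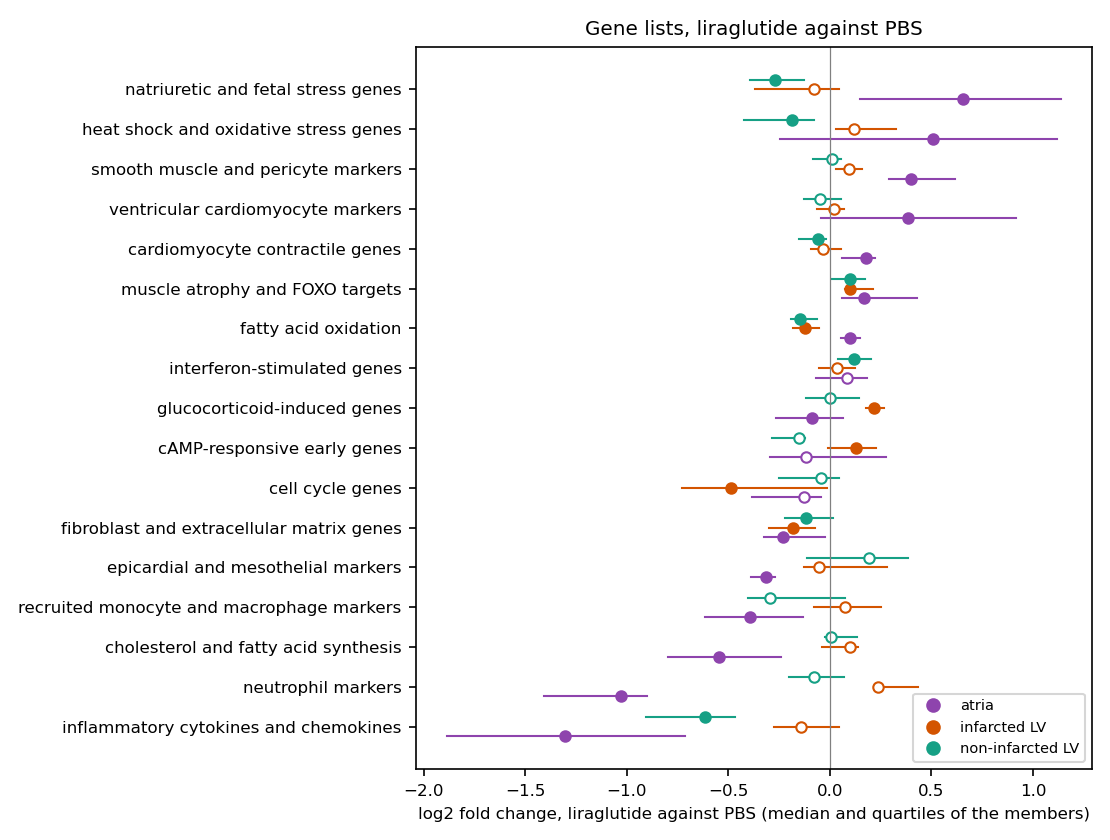
Log2 fold change with liraglutide (x axis) of 17 gene lists (y axis) in atria (purple), infarcted LV (orange) and non-infarcted LV (green), as the median over members with a bar from the lower to the upper quartile. Filled points passed camera at the preset correlation, none did with an estimated correlation; cytokines stand at -1.30 in atria, -0.142 in infarcted and -0.616 in non-infarcted LV.

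In the infarcted LV, 0 of 12988 genes passed with edgeR under liraglutide. The smallest adjusted p was 0.243, for Mtus2, which encodes a microtubule-associated protein. It stood at 153 ± 14.3 CPM with liraglutide and 101 ± 12.2 with PBS (log2 fold change 0.59, SE 0.0977) and lies on chromosome 5, 147957320 to 148316065. Next came the phosphatase Dusp18 (0.59, SE 0.11, with 55.1 ± 7.8 against 37.0 ± 3.06 CPM) and the acute-phase protease inhibitor Serpina3n (0.58, SE 0.109, with 86.6 ± 15.4 against 58.1 ± 0.887 CPM). They shared adjusted p = 0.297 with Ano10 (0.48, SE 0.093) and the efflux pump Abcb1a (0.44, SE 0.0859), and Armc2 followed (0.48, SE 0.0983, adjusted p = 0.4). On the lower side, at adjusted p = 0.403, stood the endothelial tight junction gene Cldn5 (-0.36, SE 0.0785, with 65.5 ± 2.83 against 83.7 ± 2.85 CPM) and the tubulin Tuba1a (-0.39, SE 0.0861). Cyclin D1 (Ccnd1, -0.48, SE 0.107), Ift122 (-0.57, SE 0.128), the basement membrane gene Nid2 (-0.45, SE 0.103) and the actin bundler Fscn1 (-0.48, SE 0.109) had that adjusted p as well. Nppa had 316 ± 52.8 against 433 ± 115 CPM (-0.46, SE 0.22, adjusted p = 0.957), Nppb 0.01 (SE 0.0941, 0.996), Myh6 0.07 (SE 0.122, 0.985) and Myh7 -0.10 (SE 0.51, 0.995). At an unadjusted p of 0.05 edgeR gave 681 genes (312 higher, 369 lower) against 649 by chance. Groups did not overlap for 1322 genes (10.2%, chance 10%). DESeq2 called 1 gene, voom 1, edgeR without a filter 35 and on all 18 libraries 0. Without liraglutide replicate 3, 3 genes passed, Mtus2 and Dusp18 among them.

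Gene lists in the infarcted LV moved by small amounts, with 0 members past the threshold over all genes in any of them. Glucocorticoid-induced genes rose as a list, with 15 of 16 positive (median 0.215, camera adjusted p = 2.47e-07). They had adjusted p = 0.696 with an estimated correlation. Adjusted over the list alone Sult1a1 rose (0.51, SE 0.134), with the cell cycle inhibitor Cdkn1a (0.32, SE 0.102, 443 against 355 CPM) and Klf15 (0.27) next. Muscle atrophy and FOXO targets, 14 genes, had a median of 0.0964 (camera adjusted p = 0.000236). FOXO targets had adjusted p = 0.696 with an estimated correlation. Their mitophagy receptor Bnip3 was higher adjusted over the list alone (0.38, SE 0.0858, 266 against 205 CPM), and Irs2 stood at 0.20. Early cAMP-responsive genes, 16 in number, had a median of 0.128 (camera adjusted p = 0.0163). Early genes had adjusted p = 0.861 with an estimated correlation and 0 calls adjusted over the list alone. The phosphodiesterase Pde4b had 0.36 (SE 0.105, 484 against 375 CPM), Ppargc1a 0.28 and Btg2 0.23.

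Cell cycle genes, 15 in number, fell as a list (median -0.485, camera adjusted p = 0.000236). Cell cycle genes had adjusted p = 0.696 with an estimated correlation. Adjusted over the list alone 2 fell, the proliferation marker Mki67 (-0.81, SE 0.211, 5.59 against 9.52 CPM) and topoisomerase Top2a (-0.74, SE 0.216, 3.74 against 6.08 CPM). Fibroblast and matrix genes, 19 in number, had a median of -0.184 (camera adjusted p = 0.000236). Matrix genes had adjusted p = 0.861 with an estimated correlation and 0 calls adjusted over the list alone. The collagens Col1a1 (-0.34, SE 0.0972, 188 against 238 CPM), Col1a2 (-0.29) and Col3a1 (-0.28) had the smallest p. Fatty acid oxidation had 18 of 20 genes negative (median -0.124, camera adjusted p = 0.000171), led by Decr1 (-0.22) and Acaa2 (-0.25). Oxidation genes had adjusted p = 0.861 with an estimated correlation and 0 calls adjusted over the list alone.

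Single libraries carried several of these list calls. Without PBS replicate 2 the cell cycle median was -0.0216 (adjusted p = 0.106), the fibroblast median -0.133 (0.0591) and the early gene median 0.0267 (0.257). Early genes also lost the call without liraglutide replicate 3 (0.686) or PBS replicate 3 (0.3), and fatty acid oxidation without liraglutide replicate 3 (0.0844). Other medians moved by more than 1.5 times while the call held. Early genes went to 0.26 and fibroblast genes to -0.292 without PBS replicate 1, glucocorticoid-induced genes to 0.119 without liraglutide replicate 2, and FOXO targets to 0.167 without liraglutide replicate 3. The other 26 of 32 lists did not pass (camera adjusted p from 0.0597 to 0.917), including neutrophil markers (median 0.236, 0.175) and cytokines (median -0.142, 0.209). Median and mean differed in sign for atrial (0.0241 and -0.0807) and ventricular (0.0185 and -0.00478) cardiomyocyte, endothelial (0.00628 and -0.0439), epicardial (-0.0545 and 0.0172) and neuron (0.0815 and -0.00575) markers.

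In the non-infarcted LV, too, 0 of 12919 genes passed with liraglutide and edgeR. Mtus2 again had the smallest p, at 184 ± 4.03 CPM against 130.0 ± 13 (log2 fold change 0.50, SE 0.0797, adjusted p = 0.319). The adhesion molecule Sele of activated endothelium had 5.24 ± 0.297 against 9.3 ± 0.581 CPM (-0.83, SE 0.147, adjusted p = 0.445) and Igsf1 -0.59 (SE 0.108, 0.445). Heme oxygenase Hmox1 had 53.7 ± 1.18 against 73.6 ± 9.85 CPM (-0.46, SE 0.094, 0.693). Prostaglandin D synthase Ptgds had 758.5 ± 117 against 509 ± 59.3 CPM (0.57, SE 0.119, adjusted p = 0.999). At that adjusted p also stood the antiviral Oas2 (0.44, SE 0.0968), Gbp6 (0.51, SE 0.123), cathepsin L (Ctsl, 0.35, SE 0.0855), Ift81 (0.38, SE 0.0849), Pak6 (-0.42), Rhoc (-0.33) and Rps4l (-0.51, SE 0.124), annotated as a transcribed pseudogene. Nppa (-0.39, SE 0.454), Nppb (-0.17, SE 0.395), Myh6 (0.04, SE 0.0845) and Myh7 (0.11, SE 0.134) had 0.999 too. At an unadjusted p of 0.05 edgeR gave 561 genes (248 higher, 313 lower) against 646 by chance. Groups did not overlap for 1274 genes (9.86%, chance 10%). DESeq2 called 2 genes, voom 0, edgeR without a filter 5 and on all 18 libraries 0. Leaving out a library gave 2 genes without liraglutide replicate 3 and 1 without PBS replicate 1 or PBS replicate 3.

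Cytokines fell as a list here too, and over all genes 0 members of any list passed. All 14 measured inflammatory cytokines and chemokines were negative (median -0.616, camera adjusted p = 3.37e-13). Cytokines had adjusted p = 0.393 with an estimated correlation, and a median of -0.312 without PBS replicate 2. Adjusted over the list alone 5 fell, led by Cxcl3 (-2.22, SE 0.558), Osm (-1.89), Il6 (-1.16, SE 0.334, 3.88 against 8.45 CPM) and Tgfb1 (-0.28). Fatty acid oxidation had 16 of 20 genes negative (median -0.149, camera adjusted p = 1.25e-05). Oxidation genes had adjusted p = 0.436 with an estimated correlation and 0 calls adjusted over the list alone (Hadh -0.25, Acaa2 -0.25, Slc25a20 -0.21). FOXO targets, 14 genes, had a median of 0.0997 (camera adjusted p = 0.0136). FOXO targets had adjusted p = 0.393 with an estimated correlation, and Ctsl and Bnip3 (0.25, SE 0.0738) were higher adjusted over the list alone. The call ended without liraglutide replicate 1 (0.0713) or PBS replicate 2 (0.0594). Interferon-stimulated genes had 15 of 18 positive (median 0.121, camera adjusted p = 0.0287). Interferon genes had adjusted p = 0.393 with an estimated correlation and 0 calls adjusted over the list alone (Ifit1 0.39, Rsad2 0.24). Their call was lost without liraglutide replicate 1 (0.141) or 3 (0.0968), or PBS replicate 1 (0.151) or 2 (0.111).

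Heat shock and oxidative stress genes, 14 in number, fell as a list (median -0.189, camera adjusted p = 0.0203). Heat shock genes had adjusted p = 0.591 with an estimated correlation, and Hmox1 was lower adjusted over the list alone. The call was lost without liraglutide replicate 1 (0.275) or PBS replicate 3 (0.24), and the median was -0.294 without PBS replicate 2 and -0.352 without liraglutide replicate 3. Fibroblast genes, 19 in number, had a median of -0.12 (camera adjusted p = 0.0205), with Tnc at -0.77 (SE 0.214) and Sparc at -0.23. Fibroblast genes had adjusted p = 0.874 with an estimated correlation. Their call was lost without PBS replicate 1 (0.241), PBS replicate 2 (0.511) or liraglutide replicate 3 (0.926), and the median was -0.192 without liraglutide replicate 2 and -0.213 without PBS replicate 3. Contractile genes, 18 in number, had a median of -0.0605 (camera adjusted p = 0.0214), with Casq2 at -0.27 and Mybpc3 at -0.21. Contractile genes had adjusted p = 0.874 with an estimated correlation. Contractile genes lost the call without liraglutide replicate 1 (0.148), liraglutide replicate 2 (0.0921) or PBS replicate 3 (0.722), and the median was -0.0972 without PBS replicate 2 and -0.11 without liraglutide replicate 3. Natriuretic and fetal stress genes, 13 in number, had a median of -0.272 (camera adjusted p = 0.0351), with Ankrd1 at -0.37 and Xirp2 at -0.61. Fetal stress genes had adjusted p = 0.393 with an estimated correlation. Their call was lost without liraglutide replicate 1 (0.131) or 3 (0.173), or PBS replicate 2 (0.0681) or 3 (0.139). The fibroblast, contractile and fetal stress lists had 0 calls adjusted over the list alone. The other 23 of 31 lists did not pass (camera adjusted p from 0.0504 to 0.908). Signs differed for atrial cardiomyocyte markers (median -0.187, test upward), neuron markers (median 0.0509, mean -0.0825) and smooth muscle markers (median 0.0107, mean -0.0123).

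Tested directly on all 18 libraries, the liraglutide effect differed between regions for 0 of 13920 genes in each contrast with edgeR, with 696 expected at an unadjusted p of 0.05. Between atria and non-infarcted LV, 750 genes had an unadjusted p under 0.05. The smallest adjusted p there was 0.065 for the transcription cofactor Lbh, at 0.92 in the atria and -0.27 in the non-infarcted LV (difference 1.20, SE 0.192). Lbh is 1 of the ventricular markers, and ventricular RNA in the treated atria predicts 0.41 of its 0.92 there. Next on the higher side were Prkag3 (difference 1.94, SE 0.417), the striated muscle ribosomal gene Rpl3l (1.13, SE 0.245), Arid5b (1.04, SE 0.231) and Magi3 (0.81, SE 0.185). On the lower side were Prr33 (-0.80, SE 0.174), Zdhhc9 (-0.51, SE 0.13), Mtus2 (-0.58, SE 0.149), Dusp18 (-0.62, SE 0.162) and Mustn1 (-0.79, SE 0.216), at adjusted p from 0.41 to 0.424. Between atria and infarcted LV 903 genes had an unadjusted p under 0.05, led by Pwwp3b (1.61, SE 0.278) and Lbh (1.09, SE 0.193) at adjusted p = 0.119 and Dusp18 (-0.89, SE 0.169, adjusted p = 0.192). There followed Ctbp2 (0.91), the thin filament gene Lmod3 (0.83), Arhgap20 (0.98), Smad3 (-0.66), Mtus2 (-0.67), Mustn1 (-0.93) and Cdr2l (-0.83). Between the LV regions 174 genes had an unadjusted p under 0.05, with every adjusted p at 1, and the effects on Mtus2 differed by 0.10 (SE 0.151). Among genes with a mean count of at least 50, the smallest p values in this 18-library fit belonged to Pkdrej (0.87, SE 0.278) and Adamtsl1 (0.86, SE 0.308) on the higher side and Trim68 (-0.59, SE 0.191) and Disp1 (-0.68, SE 0.244) on the lower. In the 12 LV libraries alone, a fit added after the data were seen, 0 genes passed for the contrast of LV regions, with or without the animal number as a block. With the block 385 genes had an unadjusted p under 0.05 and without it 255, against 666 by chance.

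Other tools called some of these differences. Between atria and non-infarcted LV, DESeq2 called 58 genes, voom 12 and edgeR without a filter 1. With the replicate block, here the animal number, edgeR called 1, Nab2, a repressor of early growth response factors (-0.96, adjusted p = 0.0455), chosen after its values were seen. That block takes atria and LV of 1 number as 1 animal. With liraglutide the check of atria and non-infarcted LV did not show this (correlations -0.0764 to -0.00606). Between atria and infarcted LV, DESeq2 called 30 and voom 86, and between the LV regions both called 0. Leaving out the atria of liraglutide replicate 3, the library with the most Myl2, gave 118 genes against non-infarcted and 117 against infarcted LV. In the same order, leaving out the atria of liraglutide replicate 2 gave 13 and 13, the atria of PBS replicate 3 gave 1 and 2, and infarcted LV of liraglutide replicate 3 gave 1 and 0.

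Comparing regions in the PBS animals, infarcted LV had higher immediate early, inflammatory and matrix genes than non-infarcted LV and lower genes of fatty acid use. Of 12831 genes, 6077 changed (3292 higher, 2785 lower), 1179 of the higher ones with a log2 fold change of 1 or more and 235 of the lower ones with -1 or less. Prostaglandin synthase Ptgs2 rose from 11.97 ± 2.47 to 109 ± 11.8 CPM (log2 fold change 3.22, SE 0.143, adjusted p = 2.16e-08) and lies on chromosome 1, 150100031 to 150108227. The cytokine Il6 rose from 8.54 ± 3.2 to 94.96 ± 21.6 CPM (3.47, SE 0.306, adjusted p = 0.000448). Socs3, a feedback inhibitor of cytokine signalling, rose from 99.6 ± 33.1 to 868 ± 89 CPM (3.13, SE 0.273, adjusted p = 0.000527). Arrdc2, an arrestin-domain gene on chromosome 8, 70835129 to 70839720, fell from 79.5 ± 3.08 to 8.74 ± 1.22 CPM (-3.19, SE 0.112, adjusted p = 1.48e-10). The uncoupling protein Ucp3 fell from 159 ± 23.1 to 18.2 ± 4.95 CPM (-3.13, SE 0.217, adjusted p = 5.73e-05).

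The immediate early transcription factors Nr4a2 (3.20, SE 0.195, adjusted p = 1.55e-08) and Fosb (4.10, SE 0.676, adjusted p = 0.00965) rose, as did the small GTPase Rnd1 (3.00, SE 0.221, adjusted p = 5.04e-05). Fos went from 65.6 ± 81.5 to 1172 ± 179 CPM (4.2, SE 1.13, adjusted p = 0.0413) and Egr1 from 211 ± 173 to 1660 ± 261 (2.99, SE 0.696, adjusted p = 0.0273). Hspa1a went from 38.04 ± 43.5 to 584 ± 170 CPM (4.02, SE 1.03, adjusted p = 0.0363), Hspa1b by 4.38 (SE 1.24, adjusted p = 0.0472), Dnajb1 by 3.15 (SE 0.689, adjusted p = 0.0226) and Nr4a1 by 3.22 (SE 0.658, adjusted p = 0.0185). Early genes were highest among the non-infarcted PBS libraries in replicate 3, with a mean log2(CPM + 1) of 6.02 against 5.25 and 5.07. The calls of Fos, Egr1, Hspa1a, Hspa1b, Dnajb1 and Nr4a1 were lost with a replicate block (adjusted p from 0.0551 for Nr4a1 to 0.0933 for Hspa1b). They were also lost without infarcted PBS replicate 1 (0.0597 to 0.116), infarcted PBS replicate 2 (0.0553 to 0.11), infarcted PBS replicate 3 (0.0528 to 0.107) or non-infarcted PBS replicate 1 (0.0685 to 0.0958). Without non-infarcted PBS replicate 2 they were lost too (0.0644 to 0.116), except Nr4a1. Hspa1b was further lost without a filter (0.0565).

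Also lower in the infarcted LV were the sensory channel modulator Pirt (-2.84, SE 0.249), the neuronal gene Atcay (-2.55, SE 0.299), Klhl38 (-2.18, SE 0.136), Igfals (-2.13, SE 0.299) and the peroxisomal oxidation enzyme Ehhadh (-2.08, SE 0.143). The desaturase Scd4 (-2.04, SE 0.342), the cardiac receptor Gpr22 (-2.03, SE 0.178), Ttc30b (-1.94, SE 0.178) and the protease Adamts15 (-1.81, SE 0.14) followed. Klhdc7a fell (-1.83, SE 0.479, adjusted p = 0.0161) but lost its call with all 18 libraries (0.221) and without infarcted PBS replicate 1 (0.0865), infarcted PBS replicate 3 (0.0529) or non-infarcted PBS replicate 1 (0.0508). Myh6 fell from 43650 ± 4520 to 31050 ± 2730 CPM (-0.49, SE 0.0859, adjusted p = 0.000307). Myh7 (-1.0, SE 0.487, 0.169), Nppa (0.71, SE 0.448, 0.268) and Nppb (0.95, SE 0.368, 0.101) did not pass. In alternatives, Nppa passed with the replicate block (0.000488) and Nppb with all 18 libraries and without non-infarcted PBS replicate 3 (lowest adjusted p = 4.06e-11). Myh7 passed with all 18 libraries and without infarcted PBS replicate 1 (lowest 0.00288). At an unadjusted p of 0.05 the count was 6968, and groups did not overlap for 7223 genes (56.3%, chance 10%).

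By gene list, stromal and several inflammatory groups rose in the infarcted LV. Counts are over all genes, and the counts adjusted over the list alone are the same where only 1 count is given. Of 18 cytokines and chemokines 16 rose (median 1.99, camera adjusted p = 1.14e-11), among them Lif (2.84) and the monocyte attractant Ccl7 (1.88). Cytokines had adjusted p = 0.18 with an estimated correlation. Fibroblast and matrix genes had 16 of 19 higher, 17 adjusted over the list alone (median 1.28, camera adjusted p = 4.11e-13). Matrix genes had adjusted p = 0.188 with an estimated correlation, and were led by fibrillin Fbn1 (1.55, SE 0.0843), the collagen Col1a1 (1.53, SE 0.0931, 235 against 81.0 CPM) and decorin Dcn (1.06). All 16 endothelial markers rose (median 0.947, camera adjusted p = 7.8e-12), such as the cadherin Cdh5 (1.11, SE 0.0799) and Emcn (1.17). Endothelial markers had adjusted p = 0.18 with an estimated correlation. Interferon-stimulated genes had 17 of 19 higher (median 0.889, camera adjusted p = 4.38e-06), with Cxcl10 at 3.24 and Ddx58 at 1.04. Interferon genes had adjusted p = 0.18 with an estimated correlation.

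Smooth muscle and pericyte markers had 9 of 13 higher and 1 lower (median 0.854, camera adjusted p = 1.59e-05), with Rgs5 at 1.12 and Vtn at 1.28. Pericyte markers had adjusted p = 0.18 with an estimated correlation. Early cAMP-responsive genes had 13 of 15 higher and 1 lower (median 2.08, camera adjusted p = 1.59e-05), with Pde4b at 2.08 (SE 0.114). Early genes had adjusted p = 0.363 with an estimated correlation. Resident macrophage markers had 12 of 14 higher, 13 adjusted over the list alone (median 0.656, camera adjusted p = 8.56e-05), with Adgre1 at 1.25 and C1qa at 0.68. Macrophage markers had adjusted p = 0.226 with an estimated correlation. Epicardial markers had 4 of 8 higher (median 0.888, camera adjusted p = 0.00339), with Wt1 at 1.74 and C3 at 1.36. Epicardial markers had adjusted p = 0.188 with an estimated correlation. Recruited monocytes had 4 of 12 higher (median 0.637, camera adjusted p = 0.00718), with thrombospondin Thbs1 at 2.55 and Cd14 at 1.64. Monocyte markers had adjusted p = 0.363 with an estimated correlation, and a median of 1.05 without non-infarcted PBS replicate 2. Spp1 and Arg1 of that list, chosen after their values were seen, were low in both regions. Spp1 had 0.922 ± 0.0813 CPM in infarcted and 0.676 ± 0.534 in non-infarcted PBS libraries. Arg1 had 0.0974 ± 0.0997 and 0.267 ± 0.283 CPM in the same order. Neutrophil markers did not pass as a list (3 of 13 higher, median 0.829, camera adjusted p = 0.223).

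Metabolic and contractile genes fell in the infarcted LV. Fatty acid oxidation had 19 of 20 genes lower (median -0.384, camera adjusted p = 4.11e-06), including its regulator Ppara (-1.54, SE 0.0845, 46.7 against 135 CPM) and the fatty acid carrier Fabp3 (-0.55). Oxidation genes had adjusted p = 0.278 with an estimated correlation. PPAR and fasting targets had 11 of 12 lower (median -0.743, camera adjusted p = 1.51e-07), with Plin5 at -1.11 and Txnip at -0.73. PPAR targets had adjusted p = 0.188 with an estimated correlation. Contractile genes had 17 of 18 lower (median -0.411, camera adjusted p = 9.86e-05), with phospholamban Pln at -0.68 and Ldb3 at -0.63. Contractile genes had adjusted p = 0.363 with an estimated correlation. The nuclear respiratory chain genes had 20 of 23 lower, 21 adjusted over the list alone (median -0.267, camera adjusted p = 0.00224). Respiratory chain genes had adjusted p = 0.612 with an estimated correlation. FOXO targets split, 4 higher and 5 lower of 14 (median -0.184, camera adjusted p = 0.00904), with Klf15 at -1.72 and Pik3r1 at -1.37. FOXO targets had adjusted p = 0.226 with an estimated correlation. Of 5 adipocyte markers 4 were lower (median -0.508, camera adjusted p = 0.011), with Plin4 at -0.91 and Lpl at -0.51, which cardiomyocytes also express. Adipocyte markers had adjusted p = 0.226 with an estimated correlation. The other 17 of 32 lists did not pass (camera adjusted p from 0.0524 to 0.958). Median and mean differed in sign for GLP-1 signalling (-0.157 and 0.119) and glycolysis (-0.0678 and 0.132), where the glucose transporter Slc2a1 (1.72) and Pfkfb3 (2.22) rose.

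**Figure D4:**
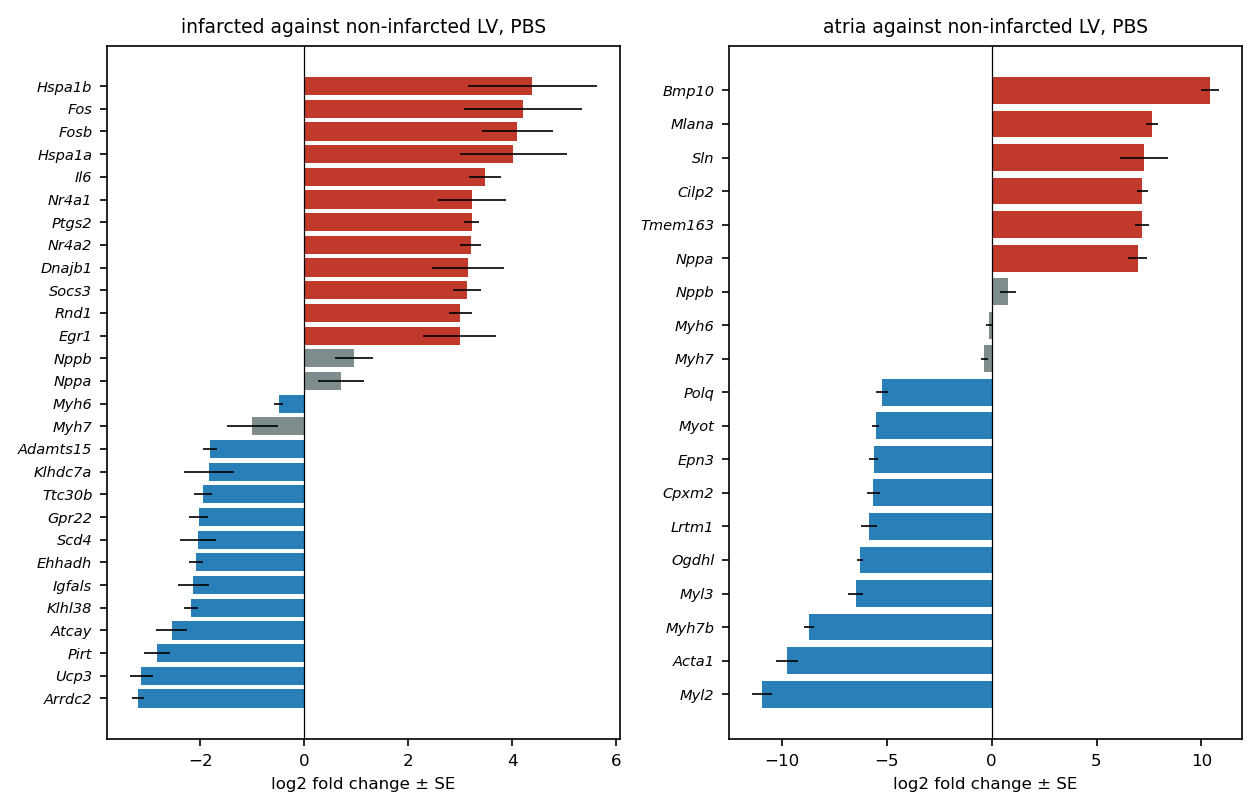
Log2 fold change (x axis, bars with SE) of named genes in PBS animals, n = 3 per group, infarcted against non-infarcted LV on the left and atria against non-infarcted LV on the right, for genes with more than 3 counts in each group. Red bars are higher, blue lower and grey bars did not pass; Hspa1b stands at 4.38 and Arrdc2 at -3.19 on the left, Bmp10 at 10.40 and Myl2 at -10.94 on the right.

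Atria of PBS animals differed from their non-infarcted LV in 6866 of 13250 genes (3457 higher, 3409 lower). Of these, 1691 had a log2 fold change of 1 or more and 1018 had -1 or less. Bmp10, a growth factor of the atrium on chromosome 6, 87428994 to 87437677, stood at 901 ± 167 CPM against 0.591 ± 0.535 (log2 fold change 10.40, SE 0.424, adjusted p = 2.56e-06). Nppa stood at 33560 ± 3800 against 268 ± 123 CPM (6.97, SE 0.446, adjusted p = 4.67e-05). Sarcolipin, Sln, the inhibitor of the calcium pump in atria, had 1779 ± 154 against 10.9 ± 9.59 CPM (7.27, SE 1.13, adjusted p = 0.00688). Lower in the atria were the ventricular light chains. Myl2, on chromosome 5, 122100951 to 122113472, had 5.33 ± 3.21 against 11210 ± 1080 CPM (-10.94, SE 0.478, adjusted p = 6.32e-06), and Myl3 75.8 ± 30.7 against 6750 ± 895 CPM (-6.48, SE 0.359).

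Further genes higher in the atria were Mlana (7.64, SE 0.281, 48.3 ± 5.54 against 0.207 CPM), the matrix gene Cilp2 (7.18, SE 0.256) and the zinc transporter Tmem163 (7.16, SE 0.343). The Langerhans cell lectin Cd207, at 9.95 ± 0.511 CPM, was at least 36.5-fold higher. Uts2b, a urotensin-related peptide, at 9.76 ± 2.38 CPM, was at least 35.8-fold higher, since neither gave a count in the LV (bounds against 3 counts per library). With 2 to 3 counts in the LV, the B cell chemokine Cxcl13 stood at 18.9 against 0.0519 CPM, Adh6b at 18.9 against 0.0633, Slc6a14 at 14.9 against 0.0519 and Dmkn at 16.2 against 0.0835. Further genes lower in the atria were skeletal actin Acta1 (-9.77, SE 0.514, 0.781 against 722 ± 325 CPM), the myosin Myh7b (-8.69, SE 0.235), Ogdhl (-6.29, SE 0.142) and Lrtm1 (-5.86, SE 0.388). Cpxm2 (-5.64, SE 0.297), Epn3 (-5.63, SE 0.217), myotilin Myot (-5.53, SE 0.168) and the polymerase Polq (-5.22, SE 0.282) followed. The ventricular transcription factor Irx4 had 0.0252 against 22.3 ± 1.95 CPM, with 1 count in the atria. Strit1, an activator of the calcium pump, had 0 counts in the atria against 12.2 ± 2.1 CPM, at least 41.8-fold lower. Nppb (0.78, SE 0.391, 0.159), Myh6 (-0.12, SE 0.126, 0.445) and Myh7 (-0.35, SE 0.154, 0.0819) did not pass. Nppb passed with the replicate block, with all 18 libraries and without non-infarcted PBS replicate 3 (lowest adjusted p = 8.97e-05). Myh7 passed with the replicate block and without atria PBS replicate 1 or non-infarcted PBS replicate 3 (lowest 0.0122). At an unadjusted p of 0.05 the count was 7620, and groups did not overlap for 8054 genes (60.8%, chance 10%).

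Cell and chamber markers set the atria apart, with counts again over all genes and the same adjusted over the list alone unless given. Epicardial and mesothelial markers had 11 of 13 higher (median 5.13, camera adjusted p = 1.56e-17), with Krt19 at 6.59 and Upk3b at 6.91. Mesothelial markers had adjusted p = 0.147 with an estimated correlation. Atrial cardiomyocyte markers had 12 of 13 higher and 1 lower (median 4.92, camera adjusted p = 2.41e-16), with Stard10 at 4.92, the peptide-amidating enzyme Pam at 3.67 and Gja5 at 3.82. Atrial markers had adjusted p = 0.147 with an estimated correlation, so that test missed even a list with 12 of 13 genes higher. Ventricular markers had 7 of 10 lower and 3 higher (camera adjusted p = 5.35e-07), with Pln at -2.50 and Lbh at -3.37. Ventricular markers had adjusted p = 0.147 with an estimated correlation. Smooth muscle and pericyte markers had 10 of 13 lower and 2 higher (median -1.31, camera adjusted p = 3.64e-06), with the channel subunit Abcc9 at -3.68 and Rgs5 at -2.15. Pericyte markers had adjusted p = 0.147 with an estimated correlation.

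Inflammatory groups were higher in the atria. Cytokines had 16 of 18 higher, 17 adjusted over the list alone (median 2.58, camera adjusted p = 3.98e-05), with the granulocyte factor Csf3 at 4.35 and Ccl7 at 2.45. Cytokines had adjusted p = 0.56 with an estimated correlation. Neutrophil markers had 12 of 13 higher (median 3.52, camera adjusted p = 0.000407), with Csf3r at 3.39 (68.1 against 6.66 CPM) and Lcn2 at 2.26. Neutrophil markers had adjusted p = 0.634 with an estimated correlation. Recruited monocytes had 12 of 14 higher (median 1.87, camera adjusted p = 3.71e-05), with galectin Lgals3 at 5.50. Monocyte markers had adjusted p = 0.511 with an estimated correlation. Neuron and Schwann cell markers had 4 of 8 higher (camera adjusted p = 0.0184), with Ncam1 at 2.44 and the noradrenaline-synthesis enzyme Dbh at 2.13. Neuron markers had adjusted p = 0.223 with an estimated correlation. Skeletal muscle markers had 5 of 6 higher and 1 lower (median 3.43, camera adjusted p = 0.0184), with the calcium pump Atp2a1 at 3.96. Skeletal markers had adjusted p = 0.511 with an estimated correlation, and lost the call without atria PBS replicate 1 (0.0509) or non-infarcted PBS replicate 3 (0.0685).

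Several lists of metabolic and contractile genes were lower in the atria than in the non-infarcted LV at the preset correlation. Fatty acid oxidation had 18 of 20 genes lower and 1 higher, 2 higher adjusted over the list alone (median -1.49, camera adjusted p = 2.41e-16), with Fabp3 at -2.34. Oxidation genes had adjusted p = 0.147 with an estimated correlation. All 23 nuclear respiratory chain genes were lower (median -0.839, camera adjusted p = 1.45e-09), with Ndufa9 at -1.15. Respiratory chain genes had adjusted p = 0.485 with an estimated correlation. Glycolysis had 12 of 20 lower and 2 higher, 14 and 3 adjusted over the list alone (median -0.611, camera adjusted p = 0.00996), with Ldhb at -1.47. Glycolysis had adjusted p = 0.555 with an estimated correlation. PPAR targets had 6 of 12 lower and 1 higher, 7 and 1 adjusted over the list alone (median -1.10, camera adjusted p = 0.000943), with the lipid droplet gene Plin5 at -2.28. PPAR targets had adjusted p = 0.147 with an estimated correlation. Contractile genes had 13 of 18 lower, 14 adjusted over the list alone (median -0.651, camera adjusted p = 3.47e-05). Contractile genes had adjusted p = 0.555 with an estimated correlation. FOXO targets had 8 of 14 lower (median -0.444, camera adjusted p = 0.0257), with Cited2 at -1.30 and Sesn1 at -1.27. FOXO targets had adjusted p = 0.223 with an estimated correlation. The other 17 of 32 lists did not pass (camera adjusted p from 0.107 to 0.981). Among them were cardiac ion channels (0.13), where the potassium channel subunit Kcnip2 (-2.47) fell, and GLP-1 signalling (0.981), where the peptidase Dpp4 (2.67) rose. Median, mean and test differed in sign for adipocyte markers (median 0.0475, mean 1.08, test downward), GLP-1 signalling (-0.148 and 0.283) and integrated stress genes (median -0.108, mean -0.0307, test upward).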

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

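The tests on the share of ventricular tissue in genes other than Myl2 and on Irs2 and fatty acid oxidation, on adipose tissue, on leukocytes and on the early genes were chosen only after the result was seen; the tests by regrouping libraries and the ventricular prediction for the fetal stress list were written beforehand.

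Between regions, the liraglutide effect on 12 of 33 gene lists differed between atria and non-infarcted LV at the preset correlation of camera, and on none with an estimated correlation (smallest adjusted p 0.113). The median differences (atria minus non-infarcted LV, log2) were -1.17 for neutrophil markers, -0.611 for cytokines, -0.55 for cholesterol and fatty acid synthesis, -0.269 for epicardial markers, -0.115 for glucocorticoid-induced genes, 0.141 for the respiratory chain, 0.216 for contractile genes, 0.272 for fatty acid oxidation, 0.439 for smooth muscle markers, 0.459 for ventricular markers, 0.757 for heat shock genes and 1.07 for natriuretic and fetal stress genes. Between infarcted and non-infarcted LV 6 lists differed (infarcted minus non-infarcted, smallest adjusted p 0.932 with an estimated correlation): respiratory chain 0.0787, glucocorticoid-induced genes 0.186, heat shock genes 0.458, recruited monocytes 0.474, cytokines 0.607 and B cell markers 0.824. Between atria and infarcted LV 11 differed (atria minus infarcted, smallest adjusted p 0.133 with an estimated correlation): neutrophil markers -1.39, cytokines -1.17, B cell markers -0.963, cholesterol and fatty acid synthesis -0.567, recruited monocytes -0.537, glucocorticoid-induced genes -0.269, contractile genes 0.142, fatty acid oxidation 0.255, smooth muscle markers 0.371, ventricular markers 0.382 and natriuretic and fetal stress genes 0.664. In the main edgeR fit no single gene differed in any of these contrasts. A real count of 0 is reached by all 100 of 100 drawn regroupings of the treatment within regions, so counting them tells nothing here. By the count at an unadjusted p of 0.05, 39 of 100 reached the real 750 (atria against non-infarcted LV), 95 the real 174 (infarcted against non-infarcted LV) and 25 the real 903 (atria against infarcted LV). These counts include the real grouping. Each region was regrouped on its own, which parts paired libraries of 1 number, so the shares cannot be read as p values. Regroupings called up to 347, 1 and 397 genes, and the high counts of some point to a structure of the samples. The differences of the cholesterol and fatty acid synthesis list rest on 1 atrial library, PBS replicate 2 with adipocyte markers, without which its atrial median was 0.00846 (adjusted p = 0.581) instead of -0.545. Other atrial list calls were also lost without 1 library. These were ventricular markers (liraglutide replicate 3), recruited monocytes (PBS replicate 2), and the epicardial, glucocorticoid-induced, contractile, fatty acid oxidation and heat shock lists.

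Ventricular genes stood higher in the atria of 2 of the 3 treated animals. Over 7 genes other than Myl2 that are at least 50 times lower in PBS atria than in PBS non-infarcted LV, the median implied share of ventricular RNA was 8.98% in liraglutide replicate 3 (Myl2 implies 8.59%), 3.27% in replicate 1 and 0% in replicate 2. These genes were chosen for low values in the PBS atria, so they cannot show whether those hold ventricular tissue. Ventricular tissue in some dissected atria is a candidate source, but single genes imply from 0.427% (Acta1) to 23.6% (Lrtm1) in replicate 3, so it stays open. That tissue does not account for Irs2, since the shares predict a log2 fold change of -5e-04 where 1.18 was measured, nor for the natriuretic and fetal stress list, with a predicted median of -0.0272 against 0.654. Acta1 of that list lies far below its predicted 5.09, at 2.31, so the estimate does not hold for every ventricular gene. For fatty acid oxidation the shares predict 0.0851 of 0.0999, but without liraglutide replicate 3 the median was 0.134 where 0.0323 is predicted, so that source stays open for this list. They predict 0.159 of 0.384 for ventricular markers (0.41 of 0.92 for Lbh, first by p in the contrast of atria with non-infarcted LV), 0.0534 of 0.103 for PPAR targets, 0.0353 of 0.0667 for the respiratory chain, 0.0717 of 0.401 for smooth muscle markers and 0.0244 of 0.176 for contractile genes, so part of these medians may come from it. An effect of liraglutide on Irs2 and the fetal stress list in the atria remains a candidate explanation, as do handling or the place of dissection, which the labels do not describe. For the 1 gene called, 10 splits of 6 libraries are too few for a share under 0.05: 2 of the 10, the real one included, gave at least as many, and the highest other, which sets liraglutide replicates 1 and 2 with PBS replicate 1 against the rest, gave 28 genes, so libraries differ along a structure other than the treatment.

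Lower cytokine and neutrophil lists in the treated atria have a mean of their medians of -1.17. Attached adipose tissue in PBS replicate 2 is argued against as the whole source, since without that library the mean is -0.897. Fewer leukocytes of every kind are argued against by the resident macrophage markers, whose median was -0.0795, while the median of 10 genes shared by leukocytes was -0.662, so fewer neutrophils and monocytes may underlie part of it. The 10 splits of the 6 libraries are too few for a share under 0.05: 2, the real one included, gave a value as far from 0, the highest other 1.69. A lower inflammatory response to liraglutide, a smaller infarct and a difference between animals remain open and untested.

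Early genes were higher in infarcted than in non-infarcted LV by a median of 2.08, above the highest median of 8 lists of cells other than myocytes (1.28, lowest 0.469, SD 0.244), which argues against a lower share of cardiomyocytes as the whole source. The lowest infarcted library lay 1.33 log2 units above the highest non-infarcted library over both treatments. Longer handling of the infarcted piece could give the same and cannot be told apart from the effect of infarction, since every infarcted library was dissected as such.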

How the results depend on the processing

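Leaving out 2 atrial libraries (liraglutide replicate 3 and PBS replicate 2) summing the LV regions and fitting the LV libraries alone were tests chosen only after the result was seen.

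For liraglutide in atria, edgeR called 1 gene, DESeq2 118, voom 36, no filter 3, all 18 libraries in 1 fit 94, the 2 left-out libraries 80, and leaving out 1 library 0 to 105 (105 without liraglutide replicate 3). In infarcted LV 0 became 1 with DESeq2, 1 with voom, 35 with no filter and 0 to 3 without 1 library; in non-infarcted LV 0 became 2 with DESeq2, 5 with no filter and 0 to 2 without 1 library; the summed LV gave 0. A threshold on the log2 fold change of 1 left 1414 genes for infarcted and 2709 for atria against non-infarcted LV; a stricter threshold leaves fewer by construction. The counts without that threshold, 6077 and 6866, were 4782 to 6051 and 5889 to 6804 without 1 library, and 5014 and 6371 with DESeq2. The effect of liraglutide in atria against non-infarcted LV, 0 with edgeR, had 58 with DESeq2, 12 with voom, 1 with no filter, 61 with the 2 left-out libraries and 0 to 118 without 1 library; against infarcted LV it had 30, 86, 0, 37 and 0 to 117. For the other moved counts the cause was not tested.

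With a replicate block (paired by number), the effect in infarcted against non-infarcted LV stayed at 0, as in the LV libraries alone with and without the animal number as a block. Liraglutide in atria gave 0 genes (Irs2 lost its call, adjusted p = 0.117), the effect in atria against non-infarcted LV 1, and Myh7 in infarcted LV a log2 fold change of 0.01409 instead of -0.10. Of 58 list calls the block changed 0, and of 105 named genes 94 kept their side of the threshold, 7 lost and 3 gained a call and 1 reversed. Liraglutide and PBS animals of 1 number are not paired: the correlation of their deviations was -0.373 to 0.148 in atria, -0.129 to -0.0633 in infarcted and -0.206 to 0.172 in non-infarcted LV.

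Directions of genes that never passed reversed; the cause was not tested. In atria Glp1r had 0.02573 and Nppa 0.01126 with voom, and without 1 library -0.6095 to 0.3487 and -0.2343 to 0.04497. In infarcted LV voom gave Nppb -0.009861 and Myh7 0.1927; without 1 library Nppb had -0.03957 to 0.09775, Myh6 -0.03826 to 0.1876 and Myh7 -0.3854 to 0.4893. In non-infarcted LV, without 1 library, Nppb had -0.3845 to 0.2799, Myh6 -0.04 to 0.09034 and Myh7 -0.02974 to 0.2672.

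Over all alternatives, named genes gave 1382 values: 1244 on the same side of the threshold, 47 weaker, 72 stronger and 19 reversed, the reversed ones all in liraglutide comparisons. Gene lists gave 478 values with the preset correlation, 436 the same and 42 weaker; with an estimated correlation 58 of 58 list calls were lost. The simulation called 19.7% of 1.5-fold changes in atria against 66.7 and 68.7% in the LV regions; atria had the larger spread between libraries (common biological coefficient of variation 0.179 against 0.0867 and 0.0959), while the deepest library is a treated atrium. Depth limits genes of few counts, such as Glp1r with 0 or 1 count per LV group.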

Other observations

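Summing both LV regions per animal number and the contrast of Mtus2 between regions were tests chosen only after the result was seen. The regroupings were written beforehand. The bound for Mtus2 in the summed counts was written before that test, but for a gene picked by its p in these same data.

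Summed over both LV regions, gene lists moved with liraglutide at the preset correlation but not with an estimated correlation (lowest adjusted p 0.67): fatty acid oxidation had a median log2 fold change of -0.145 (camera adjusted p = 7.63e-08), cell cycle genes -0.224 (0.000449), cytokines -0.249 (0.0109), contractile genes -0.0619 (0.0131), fibroblast and matrix genes -0.121 (0.0217), natriuretic and fetal stress genes -0.149 (0.0332), glucocorticoid-induced genes 0.106 (0.000312) and FOXO targets 0.11 (0.000449). No gene of 13875 passed with edgeR, with 692 at an unadjusted p under 0.05 against 694 by chance; other tools were not run on the sums.

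Mtus2 had the smallest p in each LV region, with log2 fold changes of 0.59 and 0.50, and stood at 171 ± 5.5 against 118 ± 14.1 CPM in the summed counts, with all 3 treated sums above the controls. A shared LV effect is a candidate explanation, and in the summed counts Mtus2 had a log2 fold change of 0.53 (SE 0.0808) with an adjusted p of 0.223. The bound set for the absence of such an effect, an adjusted p of 0.05 or more, was a poor choice, because a p that misses the threshold excludes nothing, so the question stays open. Both regions of an animal number are paired, so the regions are not independent evidence.

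The liraglutide fold changes in infarcted and non-infarcted LV correlated across 12626 genes (r = 0.226; genes are not independent replicates). Of 10 splits of the 6 animal numbers 1, the real split, gave a value as high, and the highest other was 0.184; 10 splits are too few for a share under 0.05.

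Regrouping was also run on the other counts, again with 10 splits each, too few for a share under 0.05. For liraglutide in infarcted and in non-infarcted LV the real count was 0, which 10 of 10 splits reach whatever the data, so that count tells nothing. Counting unadjusted p under 0.05, 4 of 10 splits reached the real 681 and 5 of 10 the real 561, the real split included. The highest other counts were 8 and 14, the 14 from the split of animal numbers 1, 2 and 3 against 4, 5 and 6. Splits with more calls than the treatment point to a structure of the samples. For infarcted against non-infarcted LV the real count was 6077 and the highest other 0 (1 of 10), and for atria against non-infarcted LV 6866 and 0 (1 of 10).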
